A study of Homo sapiens with 12 samples.

How the data were processed

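Total RNA of HaCaT cells carrying 1 of 4 short hairpin RNAs was sequenced untreated and after 24 h with H2O2 (100 µM) or with CeO2 nanoparticles (25 µg/mL), with 1 library for each of the 12 combinations. Per the submitters' processing notes, Trimmomatic 0.39, HISAT2 2.2.1, SAMtools 1.12 and HTSeq 0.11.1 were used with GRCh38; the settings of these tools and the annotation are not given in the sources used here. The deposited values are whole read counts per Ensembl gene in 2 tables of 61498 entries, 1 for H2O2 and 1 for CeO2, and both hold the untreated libraries. The untreated counts were taken from the H2O2 table; the tables differ in 1 cell, the PRDX4 entry of the untreated shUTX library (1 count against 0). Whether counting used the strand of the reads is not given in the sources used here, so overlapping and antisense genes are reported as uncertain.

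Of the 61498 identifiers, 61399 matched a gene name and 58298 the GENCODE 29 annotation, from which GRCh38 coordinates, gene types and transcript lengths were taken. Total counts per library ran from 5388335 to 7670446. A count of 0 allows up to 3 counts of the library's total, and 95% intervals of ratios of 2 libraries are exact (conditional binomial). Such intervals and limits cover counting error only, since reads copied from the same molecule are not told apart.

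Many entries of genes that every cell uses held no counts, so names were checked against a panel of 782 such genes. Runs of panel genes with at least 30 CPM were found along each chromosome with a hidden Markov model of 2 states (probability of a high gene 0.95 inside and 0.25 outside, switch 0.02). A stretch was used when it held at least 3 panel genes with a median of at least 150 CPM. This check, its limits and the restriction of gene names to the 5 stretches and the mitochondrial genome (1587 entries, 535 of them coding) were chosen after seeing the data. A first rule with 20 CPM and no limit on the median gave 7 stretches with 2578 entries and was tightened after its result was seen. The targeted genes, KMT2A, KDM6A and NFE2L2, are reported wherever they lie.

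The tests, lists of genes, rule for named genes and the other settings not marked as added later were fixed before the data were examined. Entries with at least 1 CPM in at least 3 libraries were kept (10800, of which 488 in matched stretches), library sizes were scaled by TMM, and counts were fitted with edgeR 4.0.16 (quasi-likelihood, two-sided, Benjamini-Hochberg threshold 0.05). An additive model of derivative and treatment, with 6 residual degrees of freedom, tested each exposure across the 4 derivatives and each knockdown across the 3 treatments. A model with a term for each knockdown and exposure to either agent, with 3 residual degrees of freedom, tested a changed response and is exploratory. The 3 libraries of a derivative are not separate knockdowns. All p-values called adjusted come from edgeR unless another tool is named. In each additive contrast the named genes are the 10 highest and 10 lowest log2 changes past the threshold with a mean of at least 5 CPM and the same sign in every block, and in the changed-response contrasts the 5 highest and 5 lowest. Where none passed, the 5 smallest p-values are named. Not every gene selected by this rule is given in the text. Up to 4 members of a list are given as examples.

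Lists of genes were tested with camera (limma 3.58.1, preset correlation 0.01) on voom values, with adjustment over the 21 lists that had at least 5 entries past the filter, and again with an estimated correlation and with fry. Of the 30 lists, only the mitochondrial genome list is read by name in the tests, since no other had 5 members in matched stretches. The list of NRF2 target genes is described within each derivative by its median log2 ratio (pseudocount 1 CPM) and the percentile of that median among 10000 random lists of the same size matched on mean expression. Joint calls of contrasts that share controls were set beside 20 simulations of unchanged groups and beside the overlap of independent lists.

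The tests were repeated with RLE and upper-quartile scaling, no filter beyond a count above 0, a filter at 5 CPM, DESeq2 1.42.0 (Wald test), limma-voom, fits to the compared libraries only, the untreated counts of the other table, and each library left out in turn. For the changed response only the exposed libraries were left out in turn. Within derivatives the other settings were a pseudocount of 0.1 CPM, RLE sizes, plain totals and members of at least 5 CPM. Added after seeing the data were the stretches of the first rule, adjustment over the matched stretches alone, and removal from each library of a smooth trend of log2 CPM with transcript length, fitted across 365 coding genes of the matched stretches. The code was tested on simulated counts with 200 changed entries. Apart from the planted change, library size and random spread, the simulated libraries did not differ. For H2O2 it recovered 58.2%, 85.1% and 90.9% of changes of 1.5, 2 and 4 times, with 7 false calls among 10600 unchanged entries. For shMLL1 the shares were 52.2%, 76.1% and 89.4% with 8 false calls, and for the changed response in shMLL1 0%, 28.4% and 66.7% with 3. R 4.3.3, Python 3.11.15, scipy 1.17.1, pandas 2.3.3 and numpy 2.4.6 were used.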

Results

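RNA-seq counts were analysed for 12 libraries of HaCaT cells, an established line of human keratinocytes. The line was used as 4 derivatives: one carrying a control short hairpin RNA (shControl) and one each carrying a hairpin against MLL1 (gene KMT2A, a histone H3 lysine 4 methyltransferase), UTX (gene KDM6A, a histone H3 lysine 27 demethylase) or NRF2 (gene NFE2L2, the transcription factor that drives antioxidant genes). Each derivative was left untreated, exposed to 100 µM hydrogen peroxide (H2O2) for 24 h, or exposed to 25 µg/mL cerium oxide nanoparticles (CeO2) for 24 h. There was 1 library for each of the 12 combinations, so no combination had a replicate. The labels do not state whether the libraries come from separate cultures, so every p-value below measures the spread among these libraries. By its title, the study profiled expression under oxidative stress in HaCaT cells and in cells with hairpins against these regulators. Total counts ranged from 5388335 (untreated shUTX) to 7670446 (CeO2-exposed shNRF2), and mitochondrial transcripts took between 7.41% and 10.01% of them. On log2 counts, libraries of the same derivative had a median Pearson r of 0.987 across genes (12 pairs), and libraries of different derivatives 0.972 (54 pairs). The first principal component held 29.2% of the variance and set the 3 shUTX libraries apart, at 36.1 to 39.6, against -33.5 to 1.7 for the others.

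Many genes that every cell uses had no counts under their own names. Of 782 such genes (ribosomal proteins, proteasome, respiratory chain, splicing and others), 459 had a mean under 1 CPM (a count scaled to a library total of 1e6) and 234 had no count in any library, while 191 reached 30 CPM. The genes with counts were grouped along the chromosomes: on 5 stretches, all 35 of these genes reached 30 CPM (median 278 CPM), against 156 of 747 elsewhere (median 0.135 CPM). The stretches were drawn around runs of such genes, so the share of 35 of 35 follows from how they were found, and the other genes inside them are the check. The stretches, in GRCh38 coordinates, run from 218241 to 44820428 on chromosome 5, 19375715 to 37801437 on chromosome 9, 236546 to 842545 on chromosome 11, 3247481 to 12344320 on chromosome 18 and 867630 to 6393981 on chromosome 19. Among other protein-coding genes, 66.5% of 487 inside these stretches and 32.7% of 18571 outside reached 1 CPM; for long non-coding genes and pseudogenes the shares were 9.85% and 8.31%. Genes are therefore named below only from these matched stretches and the mitochondrial genome, 488 of the 10800 entries tested, except where the text says that an entry lies outside them. Counts of entries over the whole table are given without reading their names.

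**Figure D1:**
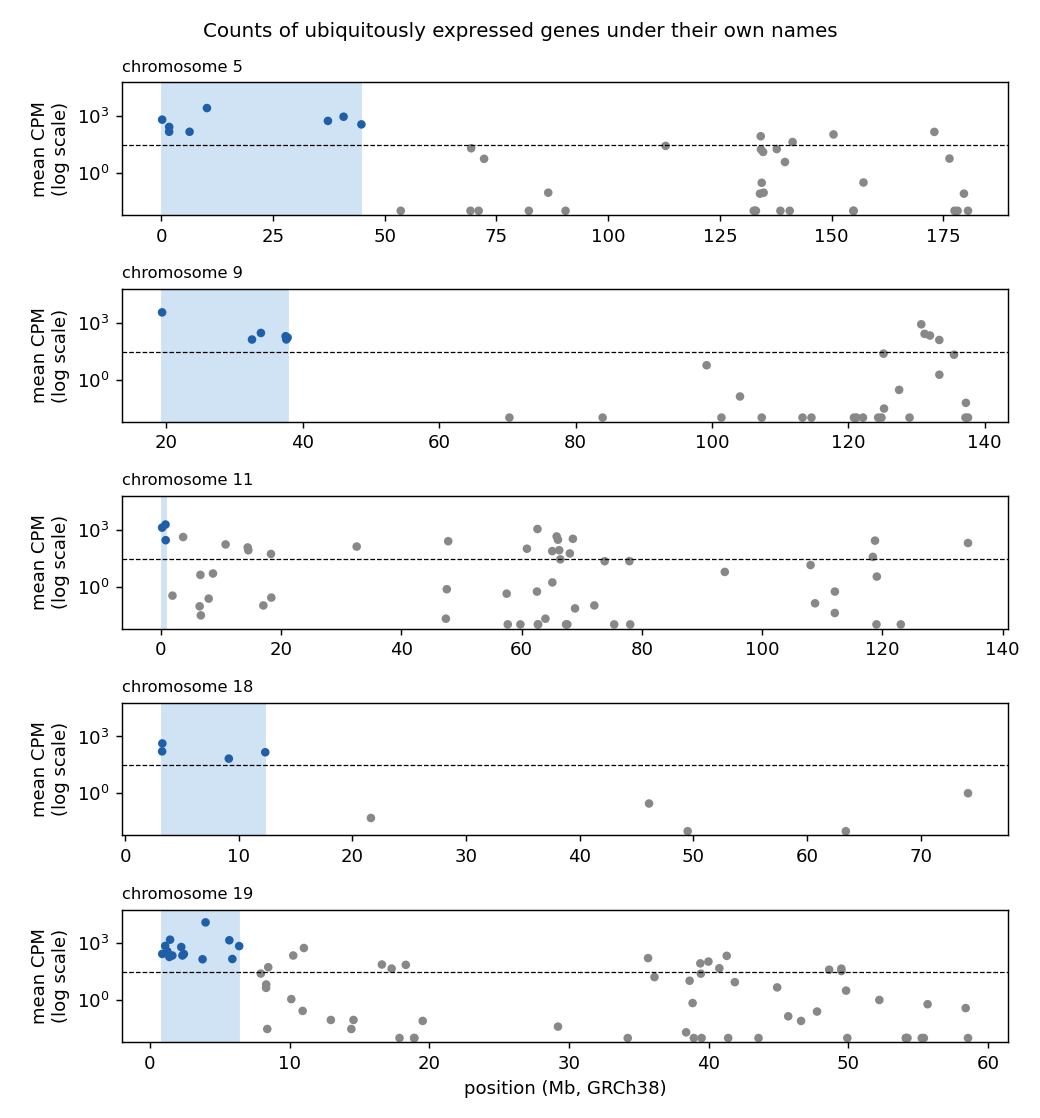
Mean CPM over the 12 libraries (log scale, values under 0.01 drawn at 0.01) of ubiquitously expressed genes against their GRCh38 position in Mb on the 5 chromosomes with a matched stretch (shaded; its genes in blue, others in grey). All 35 genes in the shaded stretches lie above the dashed line at 30 CPM, against 156 of 747 genes elsewhere in the genome.

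The silenced genes were looked at first. The KMT2A entry (chromosome 11, 118436464 to 118526832) held 464, 482 and 494 CPM in the untreated, H2O2 and CeO2 shControl libraries and 32.0, 99.7 and 35.6 CPM in the shMLL1 ones, a fall of 9.51-fold (log2 -3.25 ± 0.24 SE, edgeR adjusted p = 7.06e-07). In shUTX it held 318, 339 and 291 CPM, 1.51-fold below shControl (log2 -0.59 ± 0.21, adjusted p = 0.052). The KDM6A entry (chromosome X, 44873177 to 45112602) had 6, 5 and 6 counts in shControl and 1, 0 and 1 in shUTX, where the count of 0, in the H2O2 library, allows up to 0.526 CPM. The NFE2L2 entry (chromosome 2, 177227595 to 177392697) had 0 counts in all 3 shNRF2 libraries, and 1, 12 and 16 counts in the untreated, H2O2 and CeO2 shControl libraries. It had 1, 1 and 3 counts in shMLL1 and 1, 1 and 4 in shUTX, so a low count is not particular to shNRF2, though only shNRF2 had 0 in all 3 libraries. All 3 entries go in the direction of the labels, for NFE2L2 beyond the limit of 3 counts in the exposed libraries only. All 3 lie outside the matched stretches, and the counts of KDM6A and NFE2L2 are near the floor. Of the nearest genes of the panel described above, both of KMT2A reached 30 CPM (ATP5MG 36.6 and DDX6 263 CPM), and none of KDM6A or NFE2L2 did.

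The shMLL1 cells had much less RNA of CA9, MIR210HG, ADAMTS12 and SEMA5A than shControl cells, in each of the 3 treatments. Here and below each knockdown is a single derivative, as is shControl. An effect of silencing cannot be told apart from other differences between these derivatives. CA9, which encodes the hypoxia-inducible carbonic anhydrase IX (chromosome 9, 35673856 to 35681159), was 21.2-fold lower (log2 -4.41 ± 0.25 SE, adjusted p = 4.47e-08). MIR210HG, the host transcript of microRNA 210 (chromosome 11, 565660 to 568457), was 10.9-fold lower (log2 -3.44 ± 0.19). ADAMTS12, a secreted metalloprotease (chromosome 5, 33523535 to 33892192), and SEMA5A, a semaphorin (chromosome 5, 9035026 to 9546075), fell by 2.55 ± 0.14 and 2.53 ± 0.14 on the log2 scale. SLC9A3-AS1, BASP1, DNAH5, DAP, FSD1 and CDKN2B (the kinase inhibitor p15) had log2 changes of -2.56 to -1.21. TINCR, a gene tied to epidermal differentiation (chromosome 19, 5558167 to 5578349), was 3.82-fold higher (log2 1.93 ± 0.18, adjusted p = 7.71e-06), and PTGER4, a prostaglandin E2 receptor (chromosome 5, 40679498 to 40693735), 3.44-fold higher (log2 1.78 ± 0.12). CCDC152 rose by 1.75 ± 0.16, IRF7 (an interferon regulatory factor) by 0.89 ± 0.14, ACER2 (an alkaline ceramidase) by 0.87 ± 0.13 and NOL6 by 0.55 ± 0.07 on the log2 scale. TTC33, FUT3, PGGHG and TERT (telomerase reverse transcriptase) rose by 0.54 to 0.72.

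In the edgeR quasi-likelihood test at an adjusted p of 0.05, 127 of the 488 matched entries differed between shMLL1 and shControl, 29 higher and 98 lower. Over all entries, 1320 of 10800 did, 581 higher and 739 lower. That total was 712, 750 and 667 without the untreated, H2O2 or CeO2 shMLL1 library. FUT3 and TERT lost the call without either exposed shControl library or any 1 shMLL1 library (adjusted p 0.0588 to 0.14 and 0.068 to 0.175), and PGGHG without the H2O2 shControl (0.0544) or untreated shMLL1 library (0.0902). TERT was not called by DESeq2 (0.0609). PTGER4 and TTC33 overlap each other, and CA9, CCDC152, CDKN2B and SLC9A3-AS1 overlap ARHGEF39, SELENOP, CDKN2B-AS1 and SLC9A3 on the other strand. FUT3 has close paralogs. With strand use not given, the source of reads in these genes is uncertain.

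The shUTX cells had still lower CA9 and MIR210HG, and SEMA6B and PTPRS on chromosome 19 lay far below shControl. CA9 was 47.9-fold lower (log2 -5.58 ± 0.29, adjusted p = 8.31e-09) and MIR210HG 19-fold lower (log2 -4.25 ± 0.22). The axon guidance gene SEMA6B (chromosome 19, 4542593 to 4559808) was 10.5-fold lower (log2 -3.39 ± 0.14, adjusted p = 5.49e-10), and PTPRS, a receptor tyrosine phosphatase (chromosome 19, 5158495 to 5340803), 4.60-fold lower (log2 -2.20 ± 0.09). LRG1, next to SEMA6B (chromosome 19, 4536409 to 4540474), fell by 2.08 ± 0.17, GAMT by 1.94 ± 0.20, PLIN4 by 2.42 ± 0.36, IRX1 by 1.70 ± 0.17 and BASP1 by 1.65 ± 0.09 on the log2 scale. IFITM2 fell by 1.77 ± 0.14, but it overlaps IFITM1, a close paralog, so its counts are uncertain. PLCXD3 (chromosome 5, 41306954 to 41510628) was 7.97-fold higher (log2 2.99 ± 0.24), ONECUT3, a homeobox factor (chromosome 19, 1752373 to 1780988), 7.63-fold higher (log2 2.93 ± 0.20), and TINCR 5.74-fold higher (log2 2.52 ± 0.18). GNE, the first enzyme of sialic acid synthesis, rose by 1.37 ± 0.09, ACER2 by 1.30 ± 0.13, MTCL1 by 1.14 ± 0.16, the chemokine CCL28 by 0.92 ± 0.11 and TERT by 0.89 ± 0.17. The pseudogene HSPD1P1 (log2 0.87 ± 0.11) may share reads with its parent gene.

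The edgeR test called 195 of 488 matched entries between shUTX and shControl, 74 higher and 121 lower, and 2842 of 10800 in all, 1364 higher and 1478 lower. With only the 6 libraries of these derivatives, 117 matched entries and 1427 in all were called. GNE and PLIN4 overlap CLTA and HDGFL2 on the other strand, PTPRS another annotated gene there, and TINCR the pseudogene SNRPEP4, which leaves the source of their reads uncertain.

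The shNRF2 cells had the highest TINCR of the 4 derivatives, and lower CA9, MIR210HG and BASP1 than shControl. TINCR was 10.2-fold higher than in shControl (log2 3.35 ± 0.18, adjusted p = 5.53e-08), at 65.9, 61.8 and 61.4 CPM against 6.96, 6.40 and 5.43 CPM in untreated, H2O2 and CeO2 libraries. ONECUT3 rose by 2.19 ± 0.20, CCDC152 by 1.03 ± 0.16, ACER2 by 0.84 ± 0.13 and AQP3, the water and glycerol channel of the epidermis (chromosome 9, 33441154 to 33447633), by 0.64 ± 0.12 on the log2 scale. CA9 was 8.89-fold lower (log2 -3.15 ± 0.22), MIR210HG 4.33-fold lower (log2 -2.12 ± 0.17) and BASP1 (chromosome 5, 17065598 to 17276843) 3.38-fold lower (log2 -1.76 ± 0.09, adjusted p = 5.53e-08). GPX4, the selenoenzyme that reduces lipid hydroperoxides (chromosome 19, 1103926 to 1106791), was 1.81-fold lower (log2 -0.86 ± 0.15, adjusted p = 0.00273). ACO1, the cytosolic aconitase and iron regulatory protein (chromosome 9, 32384603 to 32454769), was 1.84-fold lower (log2 -0.88 ± 0.08). TPM2, MOB3A, RFX2, SEMA6B and RUSC2 fell by 0.80 to 0.90 on that scale (MOB3A and RFX2 overlap genes on the other strand and are uncertain). FUT3, TJP3, PGGHG, PDZD2 and IFITM1 had log2 changes of 0.54 to 0.75 with adjusted p of 0.0127 to 0.0493.

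Between shNRF2 and shControl, edgeR called 48 of 488 matched entries, 19 higher and 29 lower, and 576 of 10800 in all, 300 higher and 276 lower. Without the H2O2 shControl, H2O2 shNRF2 or CeO2 shNRF2 library the matched count was 28, 26 and 23 and the total 313, 257 and 264, and without the untreated shNRF2 library the total was 286. With only the 6 libraries of these derivatives, 16 matched entries and 154 in all were called, and ACER2 (adjusted p = 0.0636), AQP3 (0.0627) and TPM2 (0.0606) were not among them, nor were FUT3, TJP3, PGGHG, PDZD2 and IFITM1 (0.114 to 0.242). FUT3 lost its call under every omission except those of the untreated shControl, shUTX and shNRF2 libraries, TJP3 under every one except those of the untreated shControl, untreated shUTX and H2O2 shUTX libraries. PGGHG and IFITM1 lost theirs without the H2O2 shControl, H2O2 shNRF2 or CeO2 shNRF2 library, PDZD2 without the H2O2 shControl, untreated shNRF2 or H2O2 shNRF2 library, and RUSC2 without the CeO2 shNRF2 library (adjusted p = 0.0513). The adjusted p of PGGHG, IFITM1 and PDZD2 reached 0.078, 0.0845 and 0.0996 under those omissions, and those of FUT3 and TJP3 reached 0.213 and 0.215. FUT3 was not called by DESeq2 (0.0514), nor TJP3 with RLE (0.0578) or upper-quartile scaling (0.0502) or a filter at 5 CPM (0.0595). IFITM1 and FUT3 are uncertain for the paralogs named above.

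The 3 knockdowns shared several of these genes. In the matched stretches, GNE, FUT3, ACER2, CCDC152 and TINCR were higher than shControl in every knockdown, and 15 entries were lower in every knockdown, among them CA9, MIR210HG, BASP1, SEMA6B, IRX1, ACO1, RFX2, MOB3A, TPM2 and DNAH5. CA9 stood at 40.8 to 59.1 CPM in the shControl libraries and at no more than 6.34 CPM in any knockdown library. Calls in both shMLL1 and shUTX numbered 16 higher, 40 lower and 21 in opposite directions. Independent lists of those sizes would share 4.4 higher and 24.3 lower. No such number was computed for opposite directions, so those 21 calls have no reference. For shMLL1 with shNRF2 the counts were 8, 18 and 2 (1.1 and 5.8 for independent lists), and for shUTX with shNRF2 8, 20 and 5 (2.9 and 7.2). All 3 contrasts use the same 3 control libraries. In 20 simulations all 12 libraries were redrawn with no difference between derivatives. They gave a covariance of log2 changes of 0.0279 to 0.0293, against 0.118 to 0.213 observed. The simulated controls had no trait in common that sets shControl apart. The gap therefore cannot tell a shared effect of the knockdowns from such a trait of shControl. The correlations of log2 changes, 0.271 to 0.404, lay below the simulated 0.467 to 0.509. The simulations gave 0 joint calls, which says little, since unchanged groups give almost no calls. The controls are too few to be split, so part of the overlap may come from them.

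**Figure D2:**
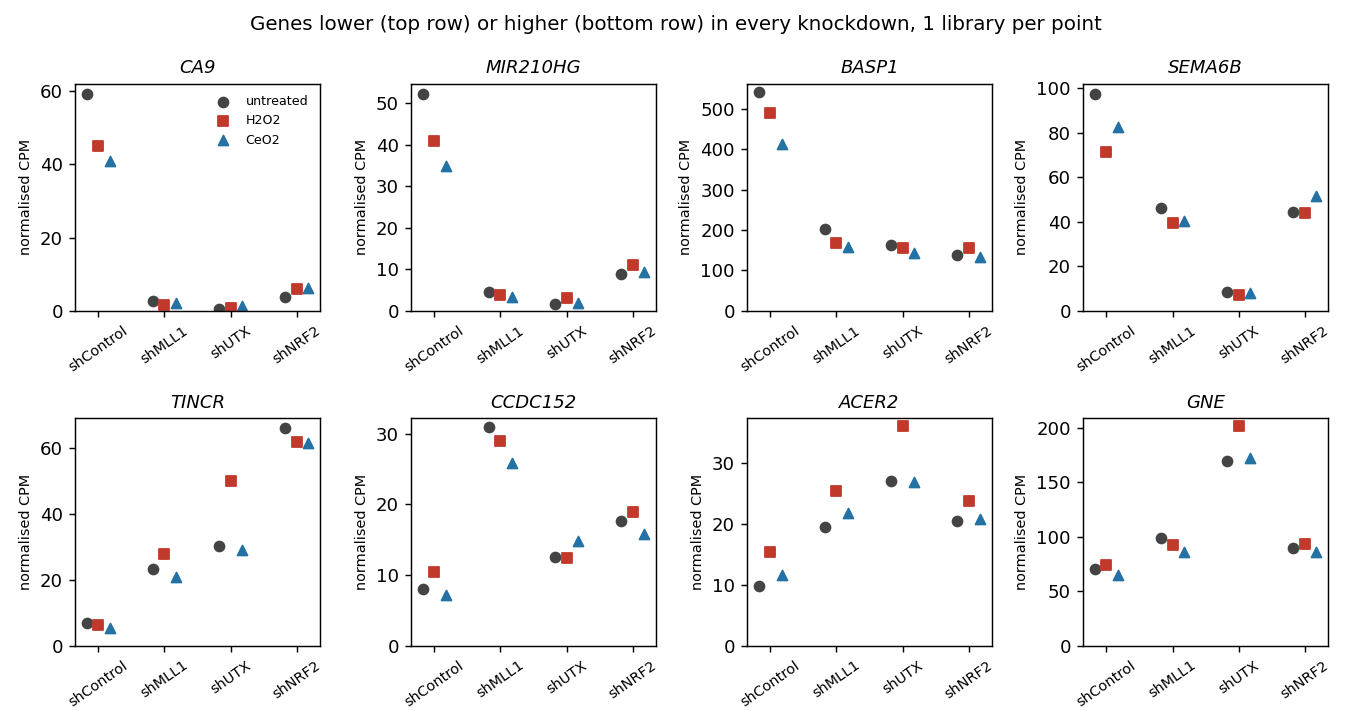
Normalised CPM (TMM library sizes, linear axis from 0) of 8 genes in each of the 12 libraries, 1 point per library, by derivative and treatment. CA9, MIR210HG, BASP1 and SEMA6B are lower in every knockdown library than in every shControl library, and TINCR, CCDC152, ACER2 and GNE are higher.

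Exposure to H2O2 for 24 h gave no gene past the threshold across the 4 derivatives. The matched genes with the smallest p were TMPRSS9, a membrane serine protease (log2 1.19 ± 0.25, adjusted p = 0.113), CPLANE1, a ciliogenesis gene (0.58 ± 0.12, 0.113), MRPL54 of the mitochondrial ribosome (-0.50 ± 0.13, 0.122) and the cold-inducible RNA-binding protein gene CIRBP (-0.28 ± 0.07, 0.127). Each had the same sign in all 4 derivatives. SNRPEP4, a pseudogene inside TINCR, was at -0.49 ± 0.12 (adjusted p = 0.122). The test by edgeR called 0 of 10800 entries and 0 of 488 matched ones. At an unadjusted p under 0.05 there were 2102 and 106 (540 entries would pass by chance). DESeq2 called 152 and 6, and limma-voom called 0 and 0. With no filter beyond a count above 0, edgeR called 651 and 36. Without the untreated, H2O2 or CeO2 shControl library edgeR called 43, 3 and 28 entries. Without the untreated shControl library 2 matched entries were called. On simulated counts, with each change equal in all 4 derivatives, this test recovered 58.2% of 1.5-fold and 85.1% of 2-fold changes. Responses that differ between derivatives were not simulated, so these shares may not hold for these libraries. TMPRSS9 and CIRBP overlap TIMM13 and CIRBP-AS1 on the other strand.

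Exposure to CeO2 nanoparticles likewise left every matched gene above the threshold. The smallest p belonged to mitochondrially encoded transcripts, MT-ND3 (log2 -0.47 ± 0.09), MT-RNR2 (-0.29 ± 0.07) and MT-CO3 (-0.29 ± 0.08), and to TMPRSS9 (0.98 ± 0.25) and BRIX1, a ribosome assembly gene (-0.31 ± 0.08), all at an adjusted p of 0.197 and with the same sign in all 4 derivatives. The 13 protein genes of the mitochondrial genome had a median log2 change of -0.22, 11 of them below 0, and 9 were lower when adjusted over the list alone, against 0 over all entries. Camera with its preset correlation called the list lower (adjusted p = 5.14e-07). It was not called with an estimated correlation (adjusted p = 0.61) or by fry (adjusted p = 0.136). For CeO2, edgeR called 2 of 10800 entries, those named TXNRD2 (log2 1.54 ± 0.23) and PDPK2P (3.68 ± 0.54), both at an adjusted p of 0.0479 and outside the matched stretches, and named here after their values were seen. Of the 488 matched entries it called 0. At an unadjusted p under 0.05 there were 1889 entries and 80 matched ones. DESeq2 called 44 and 2, limma-voom 0 and 0, and edgeR with no filter beyond a count above 0 called 543 and 28. TXNRD2 was lost with a filter at 5 CPM (adjusted p = 0.113), and both entries were lost with limma-voom (0.0769 and 0.145) or with only the 8 libraries compared (0.447 each). The count of 2 changed with each single library left out, to 10 without the untreated shControl library, 29 without the untreated shNRF2 library, 1 without the untreated or CeO2 shMLL1 library, and 0 without any other. The matched count became 1 without the untreated shControl or untreated shNRF2 library. TXNRD2 was called in none of the omissions except those of the untreated shControl and shNRF2 libraries (adjusted p 0.0614 to 0.442 in the others). PDPK2P, a pseudogene, was called in those and without the untreated or CeO2 shMLL1 library (0.0614 to 0.265 in the others). BRIX1 overlaps RAD1 on the other strand, and MT-CO3 overlaps MT-ATP6.

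The exposures were also set against each other. CDKN2B was 1.36-fold higher under H2O2 than under CeO2 in all 4 derivatives (log2 0.44 ± 0.08, adjusted p = 0.0675), which did not pass. MT-ND2 (log2 0.35 ± 0.08), MT-ND1 (0.29 ± 0.07), CBARP (0.77 ± 0.18) and ONECUT3 (0.61 ± 0.17) followed, at adjusted p of 0.24 to 0.329. The 13 mitochondrially encoded genes were all above 0, with a median of 0.14. The list was called by camera (adjusted p = 2.59e-08), not with an estimated correlation (adjusted p = 0.415) or by fry (0.27); 3 members passed when adjusted over the list alone, 0 over all entries. Of all entries edgeR called 4, named IGSF9, CDH20, RBM45 and ADGRF2 (log2 2.11, 0.65, 1.18 and 0.83, adjusted p 0.0222 to 0.0367), outside the matched stretches and named here after their values were seen, and 0 matched ones. At an unadjusted p under 0.05 there were 670 entries and 37 matched ones. DESeq2 called 21 and 1, limma-voom 4 and 0. With only the 8 exposed libraries the counts were 120 and 12, and with no filter beyond a count above 0 105 and 9. The count of 4 became 94 without the untreated shControl library, 17 without the untreated shNRF2 library, 7 without the H2O2 shControl library, and 0 without the H2O2 library of shMLL1, shUTX or shNRF2 or the CeO2 library of shUTX. CDH20 was also lost without either exposed shControl library, the untreated shUTX library or the CeO2 shNRF2 library, and ADGRF2 without the CeO2 shMLL1 or CeO2 shNRF2 library, RBM45 without the former (adjusted p 0.0539 to 0.246). The matched count became 6 without the untreated shControl library. CDKN2B and CBARP overlap CDKN2B-AS1 and STK11 on the other strand.

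Within single derivatives, exposed and untreated libraries were compared 1 against 1, which has no replicate check. GPX4 was higher in exposed shControl cells, by 1.59-fold under H2O2 (95% counting interval 1.53 to 1.65) and 1.73-fold under CeO2 (1.66 to 1.79). In shMLL1 the ratios were 1.37 and 1.14, in shNRF2 1.28 and 1.02, and in shUTX 0.946 and 0.803. TALDO1, an enzyme of the pentose phosphate pathway and the member of the NRF2 target list in a matched stretch (chromosome 11, 747329 to 765024), had ratios of 0.713 and 0.655 in shControl, 0.853 and 0.827 in shMLL1, 0.997 and 1.00 in shUTX, and 0.959 and 1.02 in shNRF2. The median log2 change of the 13 mitochondrially encoded genes under CeO2 was -0.14 in shControl (percentile 92.3 among 10000 random lists of matched expression). It was -0.33 in shMLL1 and -0.30 in shNRF2 (both at percentile 0 after rounding) and -0.02 in shUTX (percentile 14.7). With plain library totals the shControl value was 0.05. Under H2O2 the median was 0.00, -0.21, -0.015 and 0.07 in shControl, shMLL1, shNRF2 and shUTX (percentiles 98.7, 8.7, 49.4 and 98.8). In shControl it was -0.02 with RLE library sizes and 0.165 with plain library totals. The 12 entries carrying names of NRF2 target genes had medians of 0.06 and 0.38 under H2O2 and CeO2 in shControl (percentiles 54.6 and 95), -0.08 and -0.04 in shNRF2, 0.12 and -0.07 in shMLL1, and 0.25 and -0.08 in shUTX. All but TALDO1 lie outside the matched stretches. With the 7 members of at least 5 CPM only, the shControl values turned to -0.36 and -0.38 (percentiles 4 and 6.1) and the shNRF2 values to 0.048 and 0.075, so no direction is read from this list. These intervals cover counting error only and compare libraries, not conditions.

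Whether a knockdown changed the shared response to both exposures was tested with an interaction term. In shUTX, the response of GPX4 lay below that in shControl (log2 difference -0.94 ± 0.15, adjusted p = 0.00042), as did PDZD2, LMBRD2, KIF24 and LIFR, a cytokine receptor subunit (-0.66 to -0.63). MRPL54 (0.90 ± 0.14, adjusted p = 0.000346), RPP25L, ADAT3 and GADD45B (a stress-inducible gene) and the junction gene TJP3 had differences of 0.90 to 1.03. In shNRF2, ATP5F1D of ATP synthase (1.10 ± 0.12, adjusted p = 1.81e-05), CA9 (1.15 ± 0.35) and ADAT3 (1.05 ± 0.26) had positive differences. LIFR, PDZD2, CPLANE1 and MT-ND4L had differences of -0.70 to -0.68. CACTIN-AS1 (2.65 ± 0.58), FTH1P10 (1.10 ± 0.29) and SLC4A1APP1 (-4.42 ± 0.99), an antisense transcript and a pair of pseudogenes, are uncertain. In shMLL1, NDUFS7, POLR2L, MRPL54, ATP5F1D and RPLP2 had differences of 0.57 to 0.68. The counts of matched entries called were 7 in shMLL1 (7 higher, 0 lower), 108 in shUTX (94 and 14) and 126 in shNRF2 (106 and 20), and over all entries 70, 1554 and 1794. DESeq2 called 13, 83 and 83 matched entries and 65, 676 and 686 in all. The matched edgeR calls were largely the same entries. Those in both shUTX and shNRF2 numbered 83 higher, 13 lower and 0 in opposite directions (20.4 and 0.6 for independent lists). The 7 of shMLL1 were called higher in both others. Covariances of the log2 differences were 0.158 to 0.219, against 0.15 to 0.157 in simulations of unchanged groups that share controls. In shUTX 0.9% and in shNRF2 3.2% of the matched calls had the larger response in the knockdown, so nearly all lay in the response of shControl. Each of these contrasts rests on the single untreated shControl library, which had the strongest trend along transcript length: across 365 coding genes its deviations from the median library correlated with the length of the longest transcript at Spearman's rho -0.51 (genes are not independent replicates), against -0.35 in untreated shMLL1 and -0.10 to 0.22 in the other 10 libraries.

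The calls of changed response also depended on single libraries. Only exposed libraries were left out in these contrasts, so their dependence on a single untreated library was not tested. The shMLL1 count of 7 became 55 and 36 without the H2O2 or CeO2 shControl library and 0 without any 1 exposed library of shMLL1 or shUTX. The total of 70 became 676 and 373, and then 4, 5, 4 and 4, in the same order. NDUFS7, POLR2L, MRPL54, ATP5F1D and RPLP2 all lost their calls in shMLL1 without any 1 of those shMLL1 or shUTX libraries (adjusted p 0.0681 to 0.224). In shUTX, TJP3, ADAT3 and KIF24 lost theirs without the H2O2 shUTX library (0.131, 0.0618 and 0.0582) and LIFR without the CeO2 one (0.0999), which also took the total from 1554 to 822. LMBRD2 lost its call without the CeO2 shControl, either exposed shMLL1 or the CeO2 shUTX library (0.0587 to 0.219). In shNRF2, CA9 lost its call without the CeO2 shControl or CeO2 shNRF2 library (0.0936 and 0.0967) and CPLANE1 without either exposed shNRF2 library (0.0596 and 0.0656). With DESeq2, TJP3, KIF24, LIFR and LMBRD2 in shUTX (adjusted p 0.0811, 0.0923, 0.0888 and 0.141) and CPLANE1 in shNRF2 (0.171) were not called. LMBRD2 was also lost with RLE factors (0.0529) and limma-voom (0.0575), and MRPL54 and RPLP2 in shMLL1 with a filter at 5 CPM (0.0504 each) or, for MRPL54, upper-quartile scaling (0.0513). With the trend along transcript length removed, a test added after the data were seen, NDUFS7 in shMLL1, GPX4 and KIF24 in shUTX and ATP5F1D in shNRF2 were the named coding genes still called. A lost call is not a lost difference: in shUTX TJP3 was still at 0.80 (from 1.03) and LMBRD2 at -0.47 (from -0.63). NDUFS7, POLR2L, RPLP2, ADAT3, KIF24, LIFR, PDZD2, CA9 and MT-ND4L overlap other genes, which leaves their counts uncertain.

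**Figure D3:**
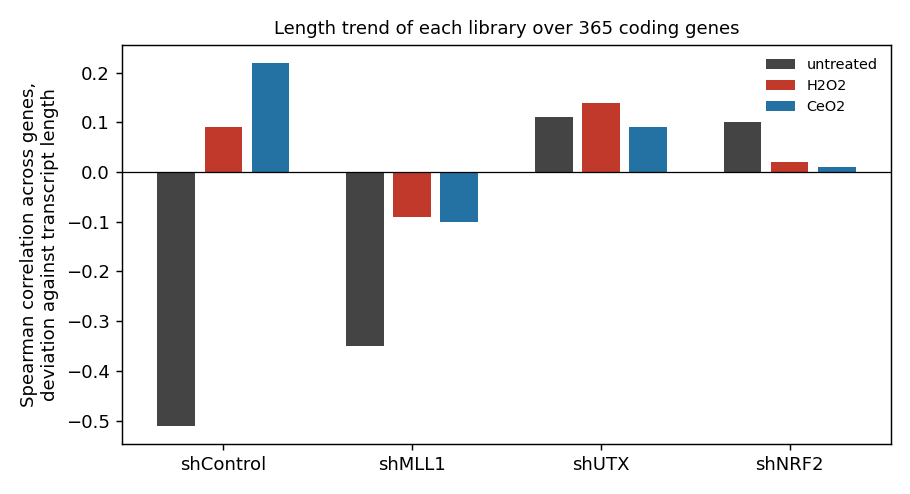
Spearman correlation, across 365 coding genes of the matched stretches, between each library's deviation from the median of the 12 libraries (log2 CPM) and the length of the longest transcript, by derivative and treatment. The untreated shControl library stands at -0.51 and the untreated shMLL1 library at -0.35, and the other 10 libraries lie between -0.10 and 0.22.

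Of 30 gene lists fixed beforehand, 21 had at least 5 entries past the filter, but the mitochondrial genome list was the 1 list with 5 or more members in matched stretches, so the other lists are given as counts. Camera with preset correlation called 0 lists for H2O2, 1 for CeO2, 2 for H2O2 against CeO2 and 4 each for shMLL1, shUTX and shNRF2. It called 2 lists each for the changed response in shMLL1 and shUTX and 0 for that in shNRF2. With an estimated correlation it called 0 in each of the 9 contrasts, and fry called 1, 2, 0, 3, 12, 6, 2, 8 and 7 in the order given. The mitochondrial genome list was lower in shMLL1 (median log2 -0.19, adjusted p = 0.00153; 0.715 with an estimated correlation) and in shNRF2 (-0.19, adjusted p = 2.86e-05; 0.369 with an estimated correlation), with 3 of 13 members lower over all entries in each, MT-CO1 and MT-ND6 among them; fry gave 0.105 and 0.0508. In shUTX 6 members were lower and 2 higher (adjusted p = 0.0547 for the list; 0.634 with an estimated correlation), and the list was called without the untreated shControl (0.00801) or CeO2 shUTX library (0.0101). MT-CO1 fell by 0.36, 0.34 and 0.35 on the log2 scale (SE 0.075 each) in shMLL1, shUTX and shNRF2. Its call was lost in shMLL1 without either exposed shMLL1 library and in shNRF2 without the H2O2 shControl library or either exposed shNRF2 library (adjusted p 0.056 to 0.0847). With only the libraries of the compared derivatives it was not called in shUTX (0.113) or shNRF2 (0.371). MT-ND6 lost its call in shMLL1 without the H2O2 shMLL1 library and in shNRF2 without the untreated or CeO2 shNRF2 library or with only the compared libraries (0.225).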

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

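All tests in this part except the splits of the libraries, the search for short matching stretches and the share of calls larger in the knockdown were chosen only after the result was seen; for the removal of the length trend, added after the data were seen, the limit was set before it was run.

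In 3 of 21 tests, 1 library stood apart from the other 3 of the same treatment. The tests took several related measures in each of the 3 treatments, on the same libraries. Chance sets apart about 1 in 20 unrelated groups, so that share is no exact guide here. Untreated shUTX had the lowest total (in units of 1e6 counts, 5.39 against 6.94 to 7.12). Untreated shControl had 12.6% of its counts in the matched nuclear stretches, against 11.84% to 11.92%. H2O2-exposed shControl had the highest total (7.34 in the same units, against 5.67 to 5.94). The length trend did not set a library apart by this measure: untreated shControl was at -0.51, a gap of 0.258 of the range, below the limit.

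The response to exposure differed between knockdown and shControl cells by the interaction test, in 7 matched entries for shMLL1, 108 for shUTX and 126 for shNRF2. These calls are not separate results: 83 higher and 13 lower entries were called in both shUTX and shNRF2, and all share the shControl libraries. In shMLL1 the log2 differences were 0.68 for NDUFS7, 0.64 for POLR2L, 0.61 for MRPL54 and ATP5F1D and 0.57 for RPLP2. In shUTX they were 1.03 for TJP3, 1.02 for RPP25L, 1.01 for ADAT3, 0.90 for GADD45B and MRPL54, -0.94 for GPX4, -0.66 for PDZD2, and -0.63 for LMBRD2, KIF24 and LIFR. In shNRF2 they were 2.65 for CACTIN-AS1, 1.15 for CA9, 1.10 for FTH1P10 and ATP5F1D, 1.05 for ADAT3, -4.42 for SLC4A1APP1, -0.70 for LIFR, -0.69 for MT-ND4L and PDZD2, and -0.68 for CPLANE1.

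A trend with transcript length, strongest in the untreated shControl library, may explain most of the changed responses. Its removal was tested in a fit to 365 coding genes alone, adjusted over them, so the counts differ from those above. The trend was removed from every library, so a true response that follows length would be lost with it. The drop in calls therefore cannot tell such a response from a fault of a single library. Before removal the differences also correlated with transcript GC content, which was not removed (Spearman's rho 0.42 in shUTX and 0.45 in shNRF2, against -0.54 and -0.59 with length). With the trend removed, calls in shUTX went from 129 to 35, of which 25 were among the 129 (19.4%) and the others new. The median size of the difference in the 129 went from 0.54 (SD 0.19) to 0.21 (SD 0.20). In shNRF2 calls went from 151 to 35, of which 31 were among the 151 (20.5%), just over the limit of 20%. By that limit length stays open in shNRF2. The shares of 19.4% and 20.5% hardly differ and rest on the same untreated shControl library, so the limit does not set the knockdowns apart. Of the named coding genes, only NDUFS7 in shMLL1 (0.55, adjusted p = 0.0171), KIF24 (-0.60, 0.0255) and GPX4 in shUTX and ATP5F1D in shNRF2 (0.56, 0.00095) stayed past the threshold. Those that lost it include MRPL54 (0.02 in shMLL1 and 0.21 in shUTX, adjusted p 0.963 and 0.33), POLR2L (0.14, 0.693), RPLP2 (0.03, 0.917) and RPP25L (0.44, 0.183). Others lost it with a larger part of the difference left. They include LIFR (-0.63 to -0.38 in shUTX, -0.70 to -0.43 in shNRF2), CA9 in shNRF2 (1.15 to 0.62) and GADD45B in shUTX (0.90 to 0.47). In shUTX, TJP3 (1.03 to 0.80, SE 0.33, adjusted p = 0.132) and LMBRD2 (-0.63 to -0.47, SE 0.18, 0.103) lost the call with most of the difference left, so their loss does not speak for the length trend. GPX4 in shUTX went against the trend, from -0.93 to -1.5 (SE 0.14, adjusted p = 1.56e-06), and is not explained by it. A response that needs the silenced gene stays open: 0.9% of the calls in shUTX and 3.2% in shNRF2 had the larger response in the knockdown, but the limit of 50% written beforehand was wrong by design, since such a response would appear in shControl alone, and it rests on the single untreated shControl library.

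Genes that every cell uses without counts under their own names may reflect reads and gene coordinates that were out of step over long stretches. Genes with and without counts switched 201 times along the chromosomes, against 234 to 326 in 100000 random orders. Reads shared with pseudogenes or paralogs would spare other families, yet 60.1% of 609 panel genes outside those families and the matched stretches lay under 1 CPM. No biological explanation was tested.

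Part of the entries with antioxidant names were highest in the exposed shControl libraries, though nearly all lie outside the matched stretches. Of 10061 entries, 14 were over 2 times every other library in both exposed shControl libraries, and 9 of them carry antioxidant names (NQO1, HMOX1, GCLM and SOD1 among them), out of 23 such entries; the rest did not show it. Names merely out of step would carry no such information (one-sided exact p = 5.61e-22, for names listed beforehand but a pattern defined after such entries were seen to show it). The other derivatives had 3, 2 and 1 entries with their own such pattern and 0 antioxidant names, too few to compare. Of the panel genes nearest to these entries, 17.6% (3 of 17) reached 30 CPM. That share cannot decide whether names and reads match over short stretches. The entries were taken from outside the runs of such genes, and a stretch shorter than the gap between panel genes would not show. Whether antioxidant genes responded to both exposures stays open. Of the 2 antioxidant genes in matched stretches, neither was over 2 times every other library. Under a looser rule, higher than every other library by any amount, 1 passed, GPX4 (1052 and 1141 CPM against at most 821), and TALDO1 did not, which is too few to decide. How these entries came to hold such counts was not resolved.

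Other splits of the same libraries were counted for each contrast. For H2O2 against untreated the real count is 0, so that 35 of 35 splits are as large decides nothing (highest other 2). For CeO2 against untreated, 3 of 35 gave at least 2 and the highest other 809, and for H2O2 against CeO2, 2 of 35 gave at least 4 and the highest other 675. By all 35 splits, chance is not excluded for CeO2 against untreated or H2O2 against CeO2. Counts of 809 and 675 lie far above the real ones. The split with 809 parts the untreated from the CeO2 library in shControl and shMLL1, and keeps the pairs of shUTX and of shNRF2 together. Derivatives were blocks in these fits, so the split with 675 did not compare derivatives as such. It set the difference of exposed from untreated libraries in shControl and shMLL1 against that in shUTX and shNRF2. Both splits thus pick up responses that differed between derivatives, which the changed-response contrasts also test, and the cause was not tested. The other splits wholly by derivative gave 0 in both contrasts, and most splits of any kind gave 0. Of the 8 splits that part the libraries of every derivative, as the real one does, 1, the real one, was as large in each of these contrasts (highest other 0), and 8 splits are too few for a share under 0.05. Each knockdown against shControl has 10 splits, too few for a share under 0.05, with 1 split as large, the real one. The real counts were 1320, 2842 and 576 for shMLL1, shUTX and shNRF2, and the highest others 1, 0 and 0.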

How the results depend on the processing

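Tests chosen only after the result was seen are the stretches of the first rule, adjustment over the matched stretches alone and removal of the length trend. Except where the construction of an alternative shows it, the cause was not tested.

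Of the values of named genes under the alternatives, 2446 kept their direction and side of the threshold, 180 fell short of it, 77 newly passed it and 10 changed sign. All 10 belong to KMT2A where it was not called. For CeO2 its log2 change of -0.07 ranged from -0.223 to 0.048 with 1 library left out, for shNRF2 -0.013 became 0.008 with limma-voom and ranged from -0.219 to 0.091, and for the changed response in shUTX and shNRF2 it ranged from -0.18 to 0.336 and from -0.023 to 0.492. Counts from the other table for the untreated libraries changed no call of a named gene.

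With no filter beyond a count above 0, the counts rose to 651 for H2O2 (36 matched), 543 for CeO2 (28) and 105 for H2O2 against CeO2 (9). They rose to 907 for shNRF2 and 218 for the changed response in shMLL1 (20 matched). For the changed response in shUTX and in shNRF2 they fell, over all and over matched entries. With at least 5 CPM, fewer entries were tested, and the counts were 0 for CeO2 and 33 for the changed response in shMLL1 (3 matched). DESeq2 called 152 (6 matched) for H2O2, 44 (2) for CeO2, 21 (1) for H2O2 against CeO2, 13 matched for the changed response in shMLL1, 676 for that in shUTX and 686 (83) for that in shNRF2. With limma-voom the count was 0 for CeO2 and 12 matched for the changed response in shMLL1, where RLE scaling gave 14 and upper-quartile scaling 4. With only the compared libraries, which leaves fewer residual degrees of freedom, the counts were 3 for H2O2, 0 for CeO2, 120 (12 matched) for H2O2 against CeO2, 1427 (117) for shUTX and 154 (16) for shNRF2. Adjusted over the matched stretches alone, 1 matched entry was called for H2O2 against CeO2 and 36 for the changed response in shMLL1. The stretches of the first rule moved no matched count by more than 1.5 times.

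The length trend was removed in a fit to the 365 coding genes alone, adjusted over them, so the counts before removal differ from those of the full fit. Calls were 16 for H2O2 (0 before), 4 for H2O2 against CeO2 (1 before), 97 for shNRF2 (61), 2 for the changed response in shMLL1 (44), 35 in shUTX (129) and 35 in shNRF2 (151).

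With 1 library left out, the counts over all and over matched entries ranged as follows. For H2O2 they were 0 to 43 and 0 to 2, for CeO2 0 to 29 and 0 to 1, and for H2O2 against CeO2 0 to 94 and 0 to 6. For shMLL1 they were 667 to 1941 and 87 to 180, for shUTX 1931 to 3088 and 152 to 220, and for shNRF2 257 to 830 and 23 to 64. For the changed response only exposed libraries were left out, and the untreated ones, on which it rests, were not. The counts were then 4 to 676 and 0 to 55 in shMLL1, 822 to 2102 and 75 to 145 in shUTX, and 1317 to 2327 and 101 to 164 in shNRF2. The libraries that moved them are named with the results.

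Camera called 0 lists in every contrast with an estimated correlation, against 1, 2, 4, 4, 4, 2 and 2 for CeO2, H2O2 against CeO2, shMLL1, shUTX, shNRF2 and the changed response in shMLL1 and shUTX. The fry test called 1, 2, 0, 12, 8 and 7 for H2O2, CeO2, H2O2 against CeO2, shUTX and the changed response in shUTX and shNRF2. With at least 5 CPM camera called 2 for shUTX, 1 for the changed response in shMLL1 and 0 in shUTX, and with RLE factors 1 in shUTX. With 1 library left out the numbers were 0 to 1 for H2O2, 1 to 2 for CeO2, 2 to 5 for shUTX and 0 to 2 for each changed response (exposed libraries only).

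The mitochondrial genome list lost its call with an estimated correlation and with fry in CeO2 (adjusted p 0.61 and 0.136), H2O2 against CeO2 (0.415 and 0.27), shMLL1 (0.715 and 0.105), shNRF2 (0.369 and 0.0508) and the changed response in shMLL1 (0.52 and 0.382). With 1 library left out its adjusted p ranged from 0.0933 to 0.968 for H2O2, 1.69e-16 to 0.00203 for CeO2, 3.68e-11 to 0.000217 for H2O2 against CeO2, 2.63e-05 to 0.0201 for shMLL1, 0.00801 to 0.189 for shUTX and 1.46e-08 to 0.00725 for shNRF2. For the changed response, with only exposed libraries left out, it ranged from 0.000419 to 0.0688 in shMLL1 (0.0688 without the H2O2 shMLL1 library) and from 0.0449 to 0.768 in shNRF2 (without the H2O2 and CeO2 shNRF2 library).

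Within derivatives, plain library totals gave mitochondrial medians of 0.053 for shControl under CeO2 (from -0.14), 0.165 for shControl under H2O2 (from 0.004; -0.024 with RLE sizes), -0.25 for shMLL1 under CeO2 and -0.12 under H2O2. Plain totals leave differences in library composition unscaled by construction. With members of at least 5 CPM only, the NRF2 target names in shControl under CeO2 had a median of -0.38. At this depth, 28.4% of simulated 2-fold changes of response in shMLL1 were recovered.

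By replicate number, no paired analysis was possible because every combination holds the same single number. Libraries were matched by derivative or by treatment, as blocks of the additive model.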

Other observations

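The tests in this part, which use the removal of the length trend, were chosen only after the result was seen.

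With the length trend removed, 16 of 365 coding genes passed the threshold under H2O2 and 0 under CeO2, which may point to an exposure response. CDKN2B was higher under H2O2 in all 4 derivatives (log2 0.35, SE 0.064, adjusted p = 0.0144), as were TMPRSS9 (1.26, SE 0.22), CPLANE1 (0.45), FUT3 (0.63), CRACR2B (0.52), ACER2 (0.51), PTGER4 (0.44), PDZD2 (0.26) and SLC12A7 (0.22). ADAMTS12 was higher in 3 of 4 derivatives (0.34). Lower in all 4 were SUB1 (-0.27), MRPL54 (-0.23), CIRBP and GATD1 (-0.21 each), and TIMM13 and VCP (-0.20 each). None of these passed without the removal. For 9 of the 16 the change shrank on removal (MRPL54 from -0.50, TIMM13 from -0.35, PDZD2 from 0.39 and CPLANE1 from 0.58 among them), so the trend had not hidden those, and the set is a hypothesis to be tested on other libraries.

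The entry of the TXNRD1 name held 592 CPM (plain totals) in untreated shControl, 927 with H2O2 and 1110 with CeO2, against 609 to 839 in the 9 knockdown libraries. The CAT entry held 76.3, 140 and 265 CPM in shControl and 44.3 to 89.5 in the others. For the NQO1 entry the values were 2.83, 40.5 and 35.6 CPM against 1.69 to 9.88. No stated rule picked these entries, and others with antioxidant names fell in exposed shControl cells. In untreated, H2O2 and CeO2 shControl libraries the AKR1C2 entry held 72.8, 63.2 and 54.1 CPM, and the TKT entry 22.3, 18.5 and 19.4. Of the 12 entries with names of NRF2 target genes, 6 were higher and 6 lower in shControl under H2O2. Under CeO2, 7 were higher and 5 lower. The entries named here lie outside the matched stretches, so what was measured under these names is uncertain.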
